A study of Triticum aestivum with 6 samples.

How the data were processed

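RNA from wheat seedling leaves was measured on 6 Affymetrix wheat genome arrays. The arrays covered the cultivars Yumai 13, HY and CYC, each with 1 array labelled 0 h post inoculation (hpi) and 1 array labelled with both 24 and 48 hpi. Groups were taken from the sample titles, which name cultivar and time. The deposited values were linear intensity values, 1 per probe set, made with MAS5 per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into a single background-corrected value. The software version, the detection calls and the target level were not given in the sources used here. The 2%-trimmed mean of the deposited intensity lay between 148.2 and 151.3 on the 6 arrays, so the arrays had been brought to a common level before deposition.

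From the deposited intensities, the 111 control probe sets named AFFX were left out and 61179 probe sets were analysed. Reporter probe sets, named RPTR, were not left out. Each array was scaled to a 2%-trimmed mean of 500, values under a floor of 100 were set to 100, and log2 was taken. The floor equalled 29.9 on the deposited scale. Differences that involve a value at the floor are lower bounds on the size of the change. Between 68.8% and 70.3% of probe sets reached the floor on each array. For arrays, the number of arrays limits the precision, and with 1 array per cultivar and time a single pair of arrays has no replicate check. Affymetrix arrays report a level relative to the other probe sets of the same array, so a change in total RNA per leaf is not measured.

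Two-sided tests used limma 3.58.1 in R 4.3.3, on the 45403 probe sets at or above the floor on at least 2 arrays. The linear model held cultivar and time without their interaction, which left 2 residual degrees of freedom. The spread in this model is how far a cultivar difference varied between times, or how far a time difference varied between cultivars. It does not measure the variation between separate plants of 1 cultivar at 1 time. Variances were moderated with a mean trend (eBayes, trend) and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The contrasts were Yumai 13 minus the mean of HY and CYC, and 24 and 48 hpi minus 0 hpi. The screens used no test. A screen counted probe sets at least 4-fold apart in all 4 time-matched pairs of arrays of a cultivar with the other cultivars. Responses were counted at 2-fold between the arrays of a cultivar. Counts for independent lists or calls took all 61179 probe sets as the base. That base includes probe sets left out of the tests as under the floor, which tends to lower these counts. A response was taken to differ in a cultivar when its log2 value lay at least 2 above, or at least 2 below, both other cultivars.

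For the screens, the time contrast and the differing responses, the genes to be named were fixed by rule before the data were examined. The rule took the 12 named probe sets per direction with the largest smallest-of-4 log2 ratio in the Yumai 13 screens. It took the 10 per direction with the largest smallest-of-3 response over cultivars, and the 5 per direction with the largest smaller difference in response of Yumai 13. It added the 1 or 2 leading probe sets without a gene name, and a gene with several probe sets was named by the probe set that ranked first. Other genes were picked by rules chosen after the data had been seen. The first took the 10 named genes per direction with the largest smaller response in CYC and Yumai 13, among them PR5, GLU1A and LOC543422. The other took the 16 genes with a name beyond a LOC symbol and a 2-fold response in at least 1 cultivar, among them XTH, PEAMT1 and CAT1. A gene name came from the platform annotation table given with the data, updated through Entrez identifiers to the RefSeq annotation of wheat cultivar Chinese Spring (IWGSC CS RefSeq v2.1). The table gave 1 gene for 1273 probe sets, several genes for 0 and none for 59906. Of the named probe sets, 1272 had an identifier found in RefSeq, and 200 had a name other than a LOC symbol. Most genes below are therefore given by a LOC symbol, the placeholder that NCBI assigns to a locus without an established symbol, and most probe sets by their number. Coordinates are not given, since no genome build is named for the array.

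Before the data were examined, 13 gene lists and 4 marker lists were fixed as word patterns. They covered pathogenesis-related proteins, peroxidases and germins, phenylpropanoid, jasmonate, immune receptors, WRKY, NAC and ERF factors, glutathione and glycosyl transferases, photosynthesis, ribosomal proteins, histones and cell division, heat shock, dehydrins and the circadian clock. The markers were for seed, epidermis, root and fungus. The naming tables held few descriptive names, and 0 of these lists had 5 tested genes. After the names had been seen, 4 lists were built from gene synonyms and tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. For comparisons of single arrays the median of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Alternatives covered floors of 50 and 200, log2 of the value plus 32, quantile normalization, the deposited scale, cross-hybridising probe sets, fold thresholds, filters, the variance trend, model terms and each array left out. Alternatives added after the data had been seen exchanged the time labels of HY, for the named genes too, left out both HY arrays, or fitted CYC and Yumai 13 alone.

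The tests were checked on simulated data for 45403 probe sets, of which 100 were changed at each size. At 4-fold and at 16-fold, limma recovered 100% of the changed probe sets for both contrasts, with 8 false calls for time and 9 for Yumai 13. The 4-fold screen recovered 16% of probe sets simulated at 4-fold and 100% at 16-fold, with 0 false calls. The simulated noise was independent and normal, with the spread that limma fitted for the level of a probe set. It held no response that differed between cultivars and no further variation in spread between probe sets. The recovery therefore checks the functions and does not give the power on the real arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.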

Results

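Leaf transcripts of 3 wheat cultivars were profiled before and after inoculation of seedlings with Blumeria graminis f. sp. tritici, the fungus that causes wheat powdery mildew. Yumai 13 is labelled susceptible, and HY and CYC are labelled resistant. Each cultivar had 1 array at 0 hpi and 1 array whose sample title names both 24 and 48 hpi, so a difference between 2 arrays carried no replicate check. The titles do not say whether RNA of both times was pooled, and each such array was treated as 1 combined sample. The 6 arrays were alike in range, with 42121 to 43000 of 61179 probe sets at or above the floor of 100 and scaled medians of 176 to 181. Pearson correlations between arrays across the 45403 tested probe sets ran from 0.93 to 0.97. A gene name was known for 1273 probe sets.

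The stated purpose of the series was to find genes very high in Yumai 13 and not in the resistant cultivars. A total of 69 probe sets were at least 4-fold higher in Yumai 13 than in both HY and CYC at both times, and 37 were at least 4-fold lower. The counts were 32 and 20 with a floor of 200, and 20 and 13 on the deposited scale with a floor of 100. None of the 69 and 37 had a gene name. The largest difference was that of Ta.10183.2.S1_at, with intensities of 9642 and 10389 in Yumai 13 and 37 or less on the other 4 arrays, a log2 difference of at least 6.59. Ta.3087.2.A1_at followed with 4995 and 4086 against 34.2 or less, a log2 difference of at least 5.35. In the opposite direction, Ta.8472.1.S1_at read 91.4 and 82.5 in Yumai 13 and 1383 to 1840 elsewhere, and TaAffx.37806.1.A1_at read 159 and 199 against 2104 to 3054. In 38 of the 69 probe sets all 4 arrays of HY and CYC were under the floor, and in 14 of the 37 both Yumai 13 arrays were.

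Among probe sets with a gene name, GA20ox1d (LOC543325), a gibberellin 20-oxidase of the pathway that makes active gibberellins, stood highest in Yumai 13. Its intensity in Yumai 13 was 1239 at 0 hpi and 380 at 24 and 48 hpi, against 225 and 121 in CYC and 117 and 163 in HY. It was at least 2-fold higher in all 4 pairs (smallest log2 ratio 1.22), but not with a floor of 200 (0.92) or on the deposited scale with a floor of 100 (0.18). It had a log2 difference of 2.18 ± 0.47 (SE) in limma and an adjusted p of 0.29. On the lower side the ribosomal protein gene RPS29 (LOC606342) ranked first, with 502 and 598 in Yumai 13 against 1299 to 1653 elsewhere, a log2 difference of -1.44 ± 0.21 with an adjusted p of 0.133 (limma). LOC606352 had -1.48 ± 0.19 with an adjusted p of 0.105, and Glc1 (LOC543469) had -1.04 ± 0.17 with an adjusted p of 0.181 (limma). The smallest-of-4 log2 ratio of the 12 leading named genes ran from 0.49 to 1.22 on the higher side and from -1.12 to -0.36 on the lower side. LOC780636, LOC543268, LOC542989, LOC100037645, LOC100037531, LOC543145, LOC780574, LOC542871, LOC606324, LOC542932 and LOC606346 made up the rest of the higher side. Of these, LOC543268, LOC100037645 and LOC100037531 were read by cross-hybridising probe sets of the same sequence cluster, so they may share a signal. The lower side held LOC606345, LOC543461, LOC100125737, LOC606397, LOC100037550, LOC543157, LOC543038, LOC100125732 and LOC543096. Another probe set of the gene had the opposite sign for LOC780574 (2 of 4), LOC542932 (1 of 1), LOC606345 (1 of 1), LOC543461 (1 of 2), LOC100037550 (1 of 2) and LOC543096 (2 of 4). None of these 24 passed the limma threshold, with adjusted p-values of 0.105 to 0.705.

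In limma, 169 probe sets differed between Yumai 13 and the mean of HY and CYC, 131 higher and 38 lower. Of the screened probe sets, 63 of the 69 and 28 of the 37 were called in the same direction. Screen and contrast use the same differences on the same arrays, so these calls follow in part from the choice. With HY and CYC set to the floor, the fitted log2 difference was 6.65 ± 0.17 for Ta.10183.2.S1_at and 5.50 ± 0.18 for Ta.3087.2.A1_at, each with an adjusted p of 0.0231 (limma). The floor made their HY and CYC responses 0, so the SE and p-value take in no spread of the HY and CYC arrays. The same holds for all 38 screened probe sets with the 4 arrays of HY and CYC under the floor. Against HY alone 126 probe sets were called, and against CYC alone 137. The count fell to 0 without any 1 of the 4 CYC and Yumai 13 arrays, and rose to 1618 without the array labelled HY 0 hpi and to 1992 without that labelled HY 24 and 48 hpi. It was 0 with a floor of 200, 0 on the deposited scale, 0 with no filter, 3 with the floor reached on all 6 arrays, and 1546 with the HY labels exchanged, a setting chosen after the data had been seen.

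HY and CYC were screened in the same way as comparison values. HY had 8 probe sets 4-fold higher and 57 lower than both others at both times, and CYC had 20 and 39. Over both times together Yumai 13 had the largest number on the higher side and HY the largest on the lower side. At single times and with the labels as given, HY had the most on either side, with 211 higher and 209 lower at 0 hpi, and 113 and 302 at 24 and 48 hpi. Yumai 13 had 95 and 86 at 0 hpi and 104 and 56 at 24 and 48 hpi, and CYC had 41 and 65 and then 49 and 51. With the HY labels exchanged, HY had 20 and 86 at 0 hpi and 69 and 139 at 24 and 48 hpi. Yumai 13 then had the most on the higher side at each time, with 103 and 106. If the calls at the times were independent, 0.161 probe sets would have been higher in Yumai 13 at both. The count of 69 for Yumai 13 was 131 against CYC alone, a setting chosen after the data had been seen.

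**Figure D1:**
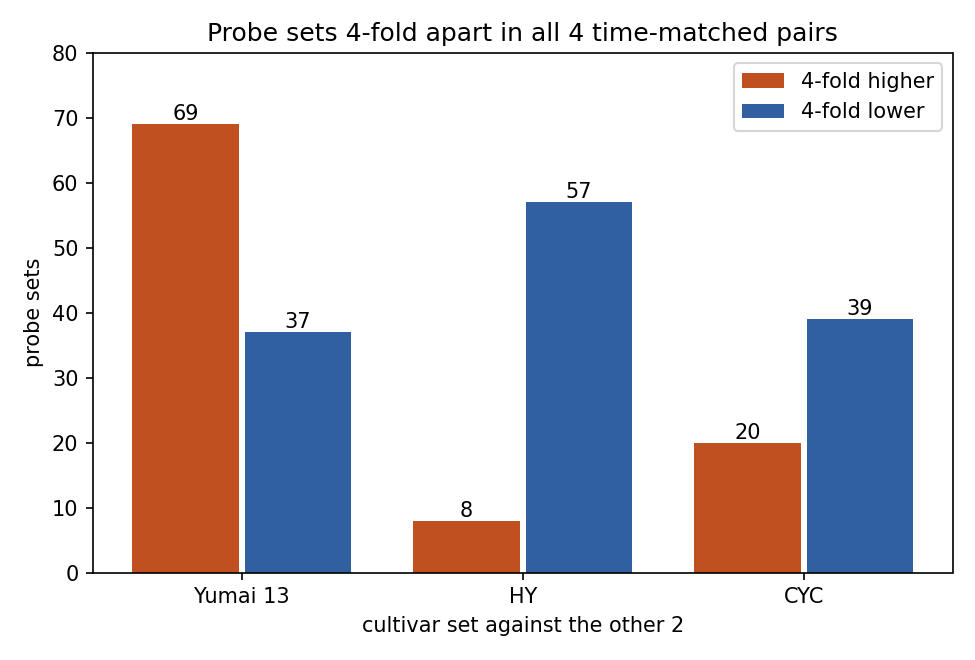
Number of probe sets (vertical axis, starting at 0) at least 4-fold higher or lower in each cultivar than in both others, in all 4 time-matched pairs of arrays. Yumai 13 had 69 higher and 37 lower, HY 8 and 57, and CYC 20 and 39.

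The time course compares arrays before and after inoculation in each cultivar. No mock-inoculated array was among the samples, so effects of inoculation and of elapsed time are not separated. The genes named here were picked after the data had been seen. In CYC and Yumai 13, PR5 (LOC543292), a thaumatin-like pathogenesis-related protein gene, was higher at 24 and 48 hpi. Its intensity was 870 and then 3800 in CYC, and 331 and then 2567 in Yumai 13. LOC543422 went from 1527 to 11686 in CYC and from 762 to 7853 in Yumai 13. On the lower side, GLU1A (LOC780595), a beta-glucosidase gene, went from 1005 to under the floor in CYC and from 703 to under the floor in Yumai 13. XTH, a gene of xyloglucan endotransglucosylase/hydrolase, which remodels the cell wall, went from 747 to 251 and from 755 to 278.

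At 2-fold, 1296 probe sets were higher and 864 lower in CYC, and 969 and 552 in Yumai 13. The lists overlapped, with 577 probe sets higher in both against 20.5 for independent lists and 314 lower in both against 7.80. Responses of CYC and Yumai 13, which share no array, correlated at r = 0.67 across probe sets, which are not independent replicates. On the deposited scale with a floor of 100, Yumai 13 had 432 higher and 376 lower. A limma fit to CYC and Yumai 13 alone, chosen after the data had been seen and with 1 residual degree of freedom, called 711 probe sets, 479 higher and 232 lower.

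In that fit LOC543422 rose by 3.15 ± 0.16 on the log2 scale (adjusted p 0.0144) and PR5 by 2.54 ± 0.24 (adjusted p 0.0307). GLU1A fell by 3.07 ± 0.19 (adjusted p 0.0147) and XTH by 1.51 ± 0.14 (adjusted p 0.0321, limma). Of the 10 named genes with the largest smaller response on each side, 8 passed on the higher side and 8 on the lower side. The higher ones were LOC543422, PR5, LOC543342, LOC543498, LOC543317, LOC606312, LOC543499 and LOC542793. The lower ones were GLU1A, LOC542947, LOC543363, LOC542855, LOC543132, LOC542812, LOC542946 and LOC542825. LOC543330, LOC543097, LOC542781 and LOC542866 did not pass. The fit averaged the same responses by which these named genes had been ranked, so passing follows in part from the choice. The other probe set of LOC543498 had the opposite sign. LOC542855 read 11790 and then 1131 in CYC and 14986 and then 2513 in Yumai 13, a log2 change of -2.98 ± 0.23 (adjusted p 0.0205). PEAMT1 (LOC543067), a phosphoethanolamine methyltransferase gene, had a log2 change of -1.18 ± 0.16 and an adjusted p of 0.0583, and CAT1, a catalase gene, had -0.92 ± 0.17 and 0.0867 (limma).

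The arrays labelled HY ran the opposite way. PR5 read 12794 on the array labelled HY 0 hpi and 134 on that labelled HY 24 and 48 hpi, and LOC543422 read 28742 and 169. GLU1A read 116 and then 779, XTH 176 and then 803, and LOC542855 685 and then 15826. By label, 1330 probe sets were higher and 1532 lower at 24 and 48 hpi in HY. The HY response correlated with that of CYC at r = -0.66 and with that of Yumai 13 at r = -0.56 across probe sets. Of the 577 probe sets higher in CYC and Yumai 13, HY was 2-fold lower in 316 and 2-fold higher in 1. Of the 314 lower in both, HY was 2-fold higher in 262 and 2-fold lower in 0.

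A limma contrast of the HY response with the mean response of CYC and Yumai 13, chosen after the data had been seen, called 3117 probe sets, 1311 above and 1806 below. PR5 had a log2 difference of -9.12 ± 0.41 (adjusted p 0.0111), GLU1A of 5.81 ± 0.32 (adjusted p 0.0119) and XTH of 3.70 ± 0.25 (adjusted p 0.0127, limma). These genes were chosen for a large response, which enlarges the contrast. The log2 response of HY itself ran from -7.41 to -0.48 in the 10 named genes highest in CYC and Yumai 13, and from 1.35 to 4.53 in the 10 lowest. CAT1 (2.46 ± 0.29, adjusted p 0.0277) and PEAMT1 (3.04 ± 0.28, adjusted p 0.019) also passed in limma. The same limma contrast for Yumai 13 and for CYC called 0 probe sets each, with 234 and 339 at an unadjusted p under 0.05. The HY response is part of the error of those contrasts (median residual SD 0.207 and 0.200, against 0.106 for HY), so the counts of 0 do not show that the responses were alike.

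**Figure D2:**
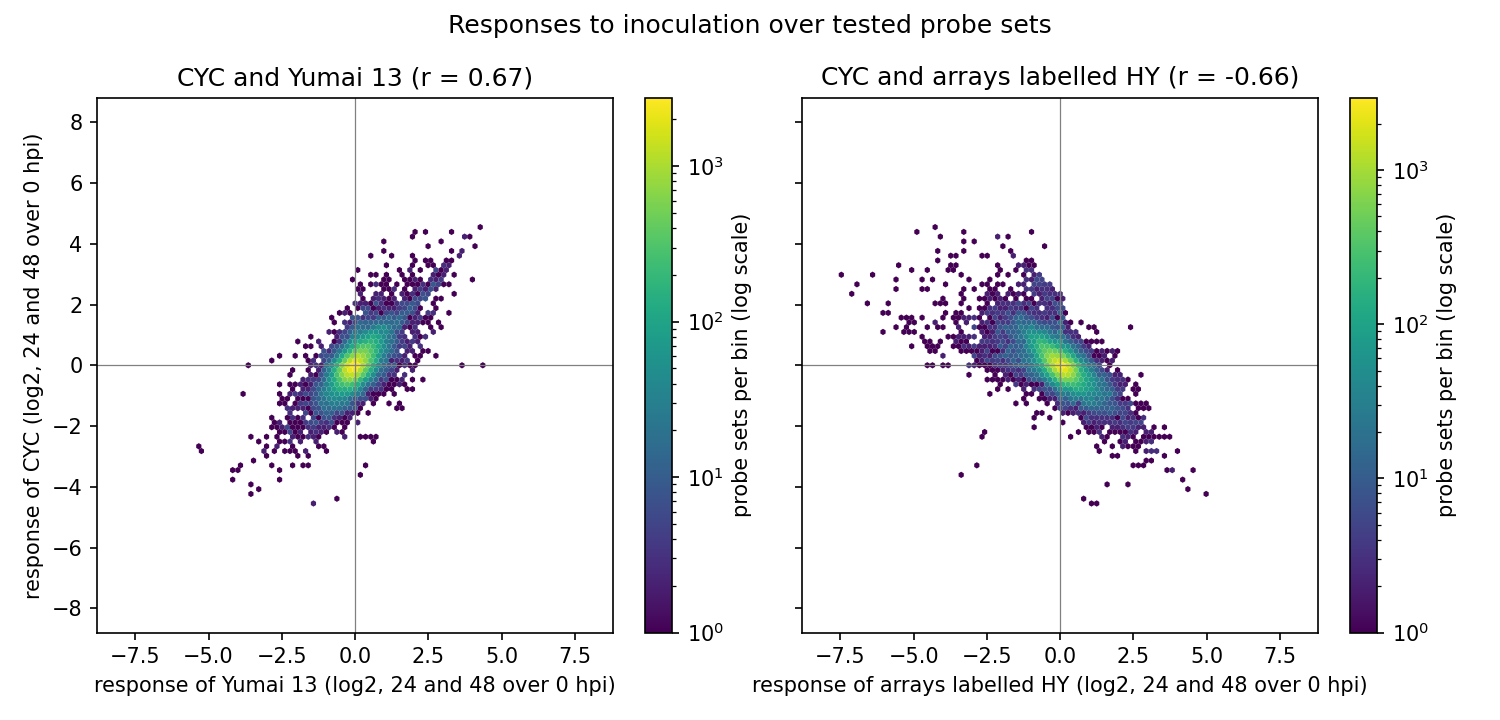
Log2 response, 24 and 48 hpi over 0 hpi, of CYC (vertical axis) against Yumai 13 (left) and against the arrays labelled HY (right). The 45403 probe sets are binned in hexagons whose colour gives the number of probe sets on a log scale. Inoculation and elapsed time are not separated. CYC and Yumai 13 lie along a rising diagonal (r = 0.67), and CYC and HY along a falling diagonal (r = -0.66).

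**Figure D3:**
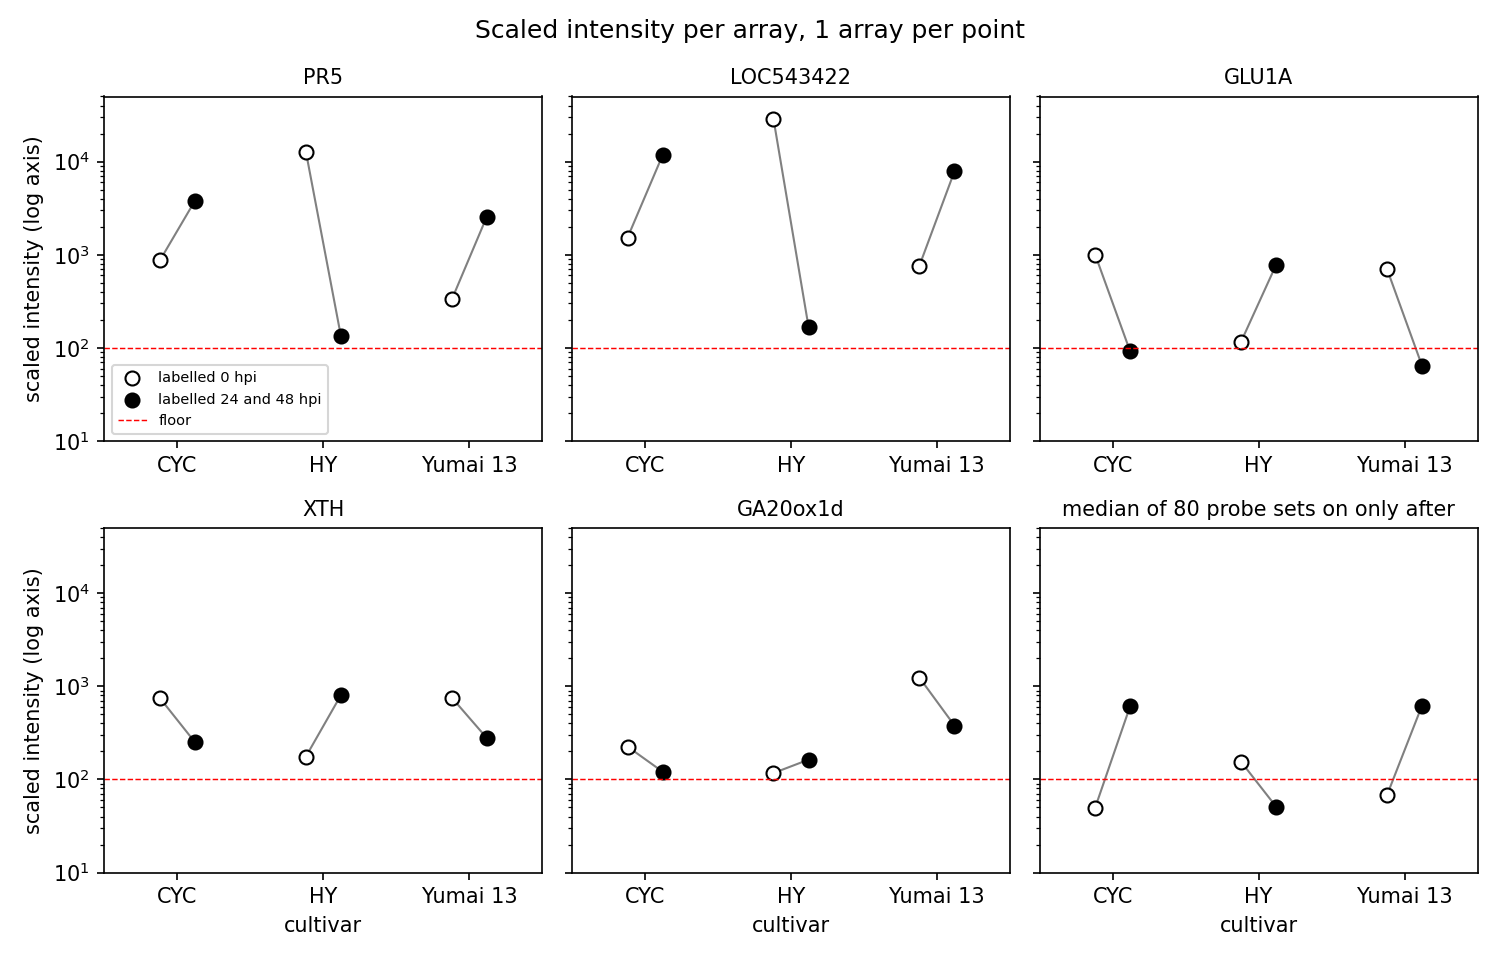
Scaled intensity (log axis) on each of the 6 arrays for PR5, LOC543422, GLU1A, XTH and GA20ox1d, and the median of the 80 probe sets under the floor at 0 hpi and at least 400 at 24 and 48 hpi in CYC and Yumai 13. Open points are arrays labelled 0 hpi, filled points those labelled 24 and 48 hpi, grey lines join arrays of a cultivar, and the dashed line is the floor of 100. In all 6 panels the arrays labelled HY ran opposite to CYC and Yumai 13.

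For independent lists over all 61179 probe sets, those under the floor included, 0.446 would be 2-fold higher in each cultivar and 0.195 lower. As labelled, 1 probe set was 2-fold higher in each of the 3 cultivars and 0 were 2-fold lower in each. That probe set, TaAffx.124475.1.A1_at, had log2 responses of 2.08 in Yumai 13, 1.13 in HY and 1.28 in CYC. The limma time contrast called 0 probe sets, with 581 at an unadjusted p under 0.05, 360 higher and 221 lower. It called 729 without the array labelled HY 0 hpi, 701 without that labelled HY 24 and 48 hpi and 0 without any other array. Among named genes, COMT1 (LOC543449), a caffeic acid O-methyltransferase gene of lignin synthesis, ranked first by the smallest of the 3 responses, with log2 responses of -0.47 in CYC, -0.47 in Yumai 13 and -1.08 in HY. On the higher side, LOC542794 had 0.56, 1.14 and 0.36 and Prx1 (LOC606328) had 0.35, 0.67 and 0.30, in the same order. The other leading genes were LOC543106, LOC543186, LOC543063, TSA (LOC542768), lgul (LOC542984), LOC780669, LOC780660 and LOC543460 on the higher side. Those on the lower side were LOC543313, LOC543332, LOC100037592, LOC542845, LOC606363, LOC543153, SAHH (adenosylhomocysteinase), LOC100037523 and LOC542904. Another probe set had the opposite sign for Prx1 (1 of 3), LOC543063 (1 of 1), LOC606363 (1 of 1) and LOC543153 (1 of 2). All 20 had an adjusted p of 1 in limma. Their shared direction rests on the HY labels as given, and exchanging those labels would leave none of the 20 with a shared direction.

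The response of Yumai 13 lay at least 2 log2 units above both other cultivars in 18 probe sets and below both in 9. With the HY labels exchanged, a setting chosen after the data had been seen, the counts were 9 and 17. The same counts were 25 and 9 for CYC and 551 and 849 for HY. The named gene with the largest deficit was LOC606391, with an intensity of 2455 and then 197 in Yumai 13, 179 and 172 in CYC, and under the floor and then 213 in HY. On the higher side, LOC100037599 went from 294 to 621 in Yumai 13 and from 1119 to 468 in CYC and 809 to 285 in HY. Only these 2 named genes reached a difference of 2 log2 units. With the HY labels exchanged, the response of LOC100037599 in Yumai 13 would lie below that of HY, while LOC606391 would still lie more than 2 log2 units below both. LOC543287, LOC543416 and LOC542994 came next, followed by LOC543422 by a probe set other than that given above. On the lower side were LOC543255, LOC543090, LOC543141 and rbcl (LOC100049018), the gene of the large subunit of Rubisco. With the HY labels exchanged, LOC543287, LOC543416, LOC542994 and LOC543422 in Yumai 13 would also lie below HY. The lower-side genes would stay below both other cultivars. Of the other tested rbcl probe sets, 13 of 17 had the opposite sign. The probe set without a name that differed most, Ta.12273.1.A1_at, read 35.5 and then 1927 in Yumai 13, 34.9 and 35.9 in CYC, and 7268 and 6549 in HY.

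Of the 17 lists of genes and markers fixed beforehand, 12 matched no probe set and 0 had 5 tested genes. The peroxidase gene PER1 (LOC543108), the only tested member of its list, had log2 responses of 0.11, -0.14 and -0.16 in Yumai 13, HY and CYC. The seed serpins Serpin-Z2A and Serpin-Z1C, the tested seed markers, had intensities of 82.4 to 206 on the 6 arrays. The 4 lists chosen after the names had been seen were photosynthesis, tubulins and histones, seed storage proteins and inhibitors, and translation factors. In the added seed list, ALP (LOC100125692) read 4105 to 5294 on the 6 arrays, and the next brightest gene, Em (LOC543480), read 226 to 284.

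The 7 photosynthesis genes, among them PsbO and PsbP of the oxygen-evolving complex, phosphoribulokinase (PRK) and fructose-1,6-bisphosphatase (FBP), stood higher in Yumai 13 than on the array labelled HY 0 hpi. All 7 lay above 0, with a median log2 difference of 0.91, the 99.9th percentile of random lists. Against CYC at 0 hpi the median was 0.01. At 24 and 48 hpi all 7 were above 0 against either cultivar, with a median of 0.38 against HY (95.3rd percentile) and of 0.27 against CYC (98.6th percentile). With the HY labels exchanged the median against HY was 0.20 at 0 hpi (92.0th percentile) and 1.01 at 24 and 48 hpi (99.95th percentile). The Calvin cycle gene FBP read 4003 in Yumai 13, 4014 in CYC and 1509 in HY on the arrays labelled 0 hpi, and the thioredoxin gene Trx-M (LOC542973) read 9688, 10262 and 3974. The contrast of Yumai 13 with the resistant cultivars gave an adjusted p of 0.0051 upward by camera at the preset correlation, 0.0139 with the HY labels exchanged, and 0.92 with an estimated correlation. On the arrays labelled HY the median response was 0.76, while it was 0.20 in Yumai 13 and -0.20 in CYC. The time contrast as labelled gave an adjusted p of 0.0273 upward by camera and 0.551 with an estimated correlation, and with the HY labels exchanged it gave 0.117 in the downward direction. Of the 10 tubulin and histone genes, 8 lay below 0 in CYC (median -0.41) and 9 in Yumai 13 (median -0.14), while 7 lay above 0 in HY (median 0.38). The beta-tubulin genes tubb1 (-0.57, -0.65 and 1.17) and Tubb4 (-0.66, -0.66 and 0.63) had some of the larger log2 responses in Yumai 13, CYC and HY. Time in CYC and Yumai 13 alone gave an adjusted p of 0.0324 downward by camera and 0.544 with an estimated correlation. The 14 seed storage and inhibitor genes had median responses of -0.04 in Yumai 13, -0.13 in CYC and 0.19 in HY. The 6 translation genes had median responses of 0.24, 0.14 and -0.11 in the same order, and neither list passed in the 3 comparisons.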

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

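The tests of the HY arrays in this part were all chosen after the results had been seen. Results here were picked out because a cultivar's response differed from that of the other cultivars. The HY response correlated with the CYC response at r = -0.66 and with the Yumai 13 response at r = -0.56 across probe sets. In limma, 3117 probe sets had an HY response unlike the mean of CYC and Yumai 13. PR5 was among them, with a log2 difference of -9.12 and an adjusted p of 0.0111.

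Scaling of a whole array, as an explanation of the opposite HY response, would move probe sets of the same level alike. In each of the 10 bins of HY level with at least 10 probe sets of each kind, the median HY response of the probe sets lower in CYC and Yumai 13 was at least 2.90 log2 units above that of the probe sets higher in them, which argues against it. Both HY arrays stood 4-fold apart from the other 4 on 62 probe sets, against at most 5 for any pair of 1 HY array with an array of another cultivar, which argues against RNA of another cultivar on either. On 891 probe sets chosen from CYC and Yumai 13 only, with 0 for their level at 0 hpi and 1 for their level at 24 and 48 hpi, the array labelled HY 0 hpi lay at 0.788 and that labelled HY 24 and 48 hpi at -0.0870, so exchanged time labels within HY are a candidate explanation. A true opposite response of HY, with PR5 high before inoculation and low after it, predicts the same correlation of -0.66. With 1 array per time in HY, that correlation cannot tell it apart from exchanged labels. Of 80 probe sets on only after inoculation in CYC and Yumai 13, 76 reached the floor on the array labelled HY 0 hpi. All 80 were under it on that labelled HY 24 and 48 hpi. They would bear on the choice only if they came from the fungus, which could not be tested by name.

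The time contrast over 3 cultivars called 0 probe sets, a count that all 10 splits of the 6 arrays into 3 and 3 reach whatever they call, so the comparison says nothing. With 10 splits a share under 0.05 cannot be reached in any case. The highest other split called 3797. It is the split that exchanges the HY arrays, so its count follows from the negative correlations of the HY response given above.

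For the probe sets that set Yumai 13 apart, tests were also chosen after the result had been seen. Both Yumai 13 arrays lay 4-fold from the other 4 on 97 probe sets, against at most 40 for any pair of arrays of different cultivars, which argues against noise of single arrays. The 40 came from the arrays of CYC and Yumai 13 labelled 24 and 48 hpi, which share a time, so it is not a noise level. The other pairs of different cultivars had at most 5. Of the 69 probe sets higher in Yumai 13, 27 had another probe set of the same sequence cluster, whose median log2 difference was 0.79, a value raised by siblings that passed the same screen. Siblings outside the screen, found for 23 of the probe sets, had a median of 0.24, which the choice lowers. Probe sequence variants and a difference in transcript level cannot be told apart here, since the choice of siblings moves the value either way.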

How the results depend on the processing

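The settings that exchanged the HY time labels (for counts and for named genes), left out both HY arrays, paired all arrays whatever their time or concern the added gene lists were chosen after the data had been seen. Counts are given in the order screened higher and lower in Yumai 13, HY and CYC, then higher in Yumai 13 at 0 hpi and at 24 and 48 hpi (69, 37, 8, 57, 20, 39, 95 and 104 as reported). At 2-fold they were 230, 153, 62, 140, 80, 120, 363 and 404, and at 8-fold 19, 8, 2, 25, 7, 11, 27 and 30. On the deposited scale with a floor of 100 they were 20, 13, 5, 16, 10, 10, 25 and 25. With a floor of 200 the counts that moved by more than 1.5 times were 32, 20, 35 (lower in HY), 23 (lower in CYC), 52 and 53. Without both HY arrays the Yumai 13 counts were 131, 81, 197 and 184. With each array left out in turn they ran from 71 to 104 and 38 to 86 for Yumai 13, 10 to 211 and 60 to 302 for HY, and 22 to 49 and 43 to 65 for CYC. The contrast of Yumai 13 with the resistant cultivars (169 calls) gave 256 with a floor of 50, 0 with a floor of 200, 0 on the deposited scale, 0 with no filter, 3 with the floor reached on all 6 arrays, 109 without the variance trend and 454 without the time term. It gave 736 without HY, 1546 with the HY labels exchanged, which included all 169, and 0 to 1992 with each array left out. Time over 3 cultivars (0 calls) gave 3797 with the HY labels exchanged and 0 to 729 with an array or a cultivar left out, where 711 was the count without HY. Responses of Yumai 13, HY and CYC (1521, 2862 and 2160) were 808, 1821 and 1322 on the deposited scale and 299, 546 and 338 at 4-fold. The shared response of 1 probe set was 0 with a floor of 200, with log2 of the value plus 32, on the deposited scale and at 4-fold, 578 with the HY labels exchanged and 891 in CYC and Yumai 13 alone. The 27 probe sets whose response differed in Yumai 13 became 16 with a floor of 200, 11 on the deposited scale, 1 at 16-fold and 73 without HY, and 26 with the HY labels exchanged, then 9 above and 17 below. The 3 calls of the added gene lists became 0 with an estimated correlation. The deposited scale with the same floor and the floor of 200 raise the floor relative to the signal, so fewer probe sets can pass. Leaving out an array, or both HY arrays, drops pairs that a probe set must pass, so the screen counts can only rise. A changed fold threshold likewise moves the counts by construction. For the other settings the cause was not tested. Of 205 alternative values of these counts, 123 stayed within 1.5 times the reported count and 82 moved by more. Of 569 alternative values of 101 results for named genes and probe sets, 524 stayed within 0.58 log2 units of the reported value, 45 moved by more and 0 reversed, with the HY time labels as given. With those labels exchanged the 28 screen results kept their sign. The 20 from CYC and Yumai 13 alone use no HY array, so the exchange could not change them. All 24 shared time responses lost their common direction (TaAffx.124475.1.A1_at became -1.13). That follows by construction, since they were picked for a direction shared with HY. Of the 10 differing responses of named genes 5 turned, all of them on the higher side, with LOC100037599 at -0.43. Of 16 HY responses minus those of the other cultivars 12 turned, as the exchange turns the HY response by construction. Among them were PR5 4.04, XTH -0.68, PEAMT1 -0.68, GAPN -1.49, CAT1 -0.61, tubb1 -0.56, Trx-M -1.01, FBP -1.003 and PsbP -0.95. The time contrast compared arrays within each cultivar, and it called 0 without the cultivar term as well. Alternatives for the gene lists fixed beforehand gave no value. Signal near background limits the low probe sets, since a difference is only a bound where an array is at the floor.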

Other observations

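The tests in this part were all chosen after the results had been seen. A group of 80 probe sets was under the floor at 0 hpi and at least 400 at 24 and 48 hpi in both CYC and Yumai 13, with HY not used to choose them. Their median intensity was 613 in CYC and 622 in Yumai 13 after inoculation, and 49.7 and 67.9 before. The median log2 ratio of CYC to Yumai 13, resistant and susceptible by label, was 0.01 after inoculation. The choice asked for at least 400 in both and left out probe sets weak in either, which draws this ratio toward equality. It therefore does not show an equal amount in both cultivars. None of the 80 had a gene name. Ta.22668.1.S1_a_at, the brightest, read 27.3 and then 1580 in CYC, and 27.6 and then 1690 in Yumai 13.

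On the array labelled HY 0 hpi, 76 of the 80 probe sets reached the floor, with a median of 155, and on that labelled HY 24 and 48 hpi all 80 were under it, with a median of 51.0. The log2 ratio of the array labelled HY 0 hpi to the mean of CYC and Yumai 13 after inoculation had a median of -2.05 and an interquartile range of 0.30, against 1.03 over the 327 other raised probe sets that were at least 400 there, and 2.94 over the 55 of them with a rise no smaller than the least in the block. The log2 ratio of CYC to Yumai 13 after inoculation also had a narrower interquartile range in the block, 0.20 against 0.59 over the 55. The 55 were matched on rise but not on level, with a median of 1666 in CYC after inoculation against 613. Whether level or the choice of the block narrows the ratios was not tested. The near-constant HY ratio of the block may come from a single common source of RNA. Its amount would be lower on the array labelled HY 0 hpi than in CYC and Yumai 13 after inoculation. With the baseline taken off, that array held a median share of 0.168 of the rise for the block (upper quartile 0.189), against 0.824 for the 327 (lower quartile 0.396) and 0.936 for the 55. The 327 lay apart from the block, but the lower quartile of the 55, 0.181, overlapped it, so a part of the wider response cannot be told apart from a separate source. The fungus is a candidate source that could not be tested by name, because the list of fungal markers matched no probe set.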
